A study of Mus musculus with 6 samples.

How the data were processed

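RNA from sorted cells of OLV2-1, a mouse embryonic stem cell line with the fluorescent reporter Venus knocked into the Oct4 (Pou5f1) locus, was measured on 6 Affymetrix 3' expression arrays, 2 per group. The labels name 3 groups: undifferentiated embryonic stem cells (ESC), epiblast stem cell-like cells (EpiSC-like) from aggregates after 3 days in SFEBq, a serum-free suspension culture of quickly reaggregated cells used for neural induction, and the Oct4-Venus-positive fraction of such aggregates after 7 days. Per the labels' protocols, EpiSC-like cells were sorted as Venus-positive and negative for Pecam1 (CD31), a surface protein of naive stem cells, and the day 7 cells as Venus-positive with no Pecam1 gate named. The ESC are labelled as Venus-positive, and the sorting protocol adds CD31-positive. Per the same protocols, ESC and day 3 aggregates were dissociated with trypsin, left for 1 hour in medium and stained with antibody, whereas day 7 aggregates were dissociated with EDTA in saline. The labels do not say that arrays of a group came from separate cultures, so p-values measure only the spread between these samples.

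The deposited values are linear signal intensities per probe set, and per the submitters' processing notes Affymetrix Expression Console (version 1) was used, with neither its role nor its algorithm given in the sources used here. The mean intensity of the deposited values, after removal of 2% of probe sets at each end, was between 499.793 and 499.832 on every array, so each array had been scaled to one trimmed mean before deposition. The genome build behind the probe annotation is not given in the sources used here, and no coordinates are printed. Detection calls and scanner files were not used here. The precision of each value is limited by the number of arrays.

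Of 45101 probe sets, 64 control probe sets were left out of the tests. A table of the platform's annotation gave 1 gene to 34945 of the others and several genes to 932. Over all 45101 probe sets, controls included, 9211 had no gene in it. Genes were named only from probe sets with 1 gene. Symbols were checked by gene identifier against the RefSeq table of assembly GRCm38.p6, which held 34741 of those 34945 probe sets and changed 0 symbols. Each gene was represented by its probe set with the highest mean over all 6 arrays, which gave 18194 genes. Of the 75 calls of named genes, 20 concerned genes with several probe sets above the median of all genes, and in 20 of those 20 all such probe sets changed in one direction, though not always by the same amount.

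Values were transformed as log2(signal + 16), so that a fold change on this scale understates the change of dim genes. limma (version 3.58.1, R 4.3.3) was fitted to all 6 arrays with 3 group means and no block, and moderated with eBayes. Its 3 contrasts, EpiSC-like minus ESC, day 7 minus ESC and day 7 minus EpiSC-like, were called at a Benjamini-Hochberg adjusted p under 0.05 over the 18194 genes, with no filter on dim genes. Values in the text are log2 differences ± the standard error of that fit, and means ± SD of signal over 2 arrays. The fit had 3 residual degrees of freedom.

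Before the data were examined, 22 gene lists and 7 cell type lists were written from textbook knowledge. The gene lists were naive pluripotency, core pluripotency, formative and primed epiblast, anterior neuroectoderm, pan-neural progenitor, midbrain hindbrain and caudal, neurogenesis and neurons, FGF-ERK response, Nodal-activin, BMP response, Wnt response, Notch, retinoic acid, DNA methylation machinery, 2-cell-like genes, imprinted genes, glycolysis, mitochondrial respiratory chain, cell cycle, p53 targets, ribosomal proteins, and cell dissociation and immediate early genes. The cell type lists were primitive streak and mesendoderm, primitive and visceral endoderm, trophoblast, primordial germ cells, neural crest and surface ectoderm, fibroblast and mesenchyme, and blood and endothelium. Of their 448 entries 34 had no probe set with 1 gene. Each list was tested in each contrast with limma's camera, two-sided, at the preset correlation of 0.01, and the 87 p-values were adjusted together. With an estimated correlation 0 of the 87 tests passed, and with fry, which asks whether the genes of a list move on balance one way, 0 passed too.

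The genes named were fixed by rule, also before the data were examined. They are Pou5f1, Pecam1 and 11 stage markers in every comparison, of which T was not measured; per comparison the 10 largest rises and 10 largest falls among called genes whose higher group mean lay at or above the median of all genes (log2 of 7.58), clone names left out; per list up to 4 called members and any uncalled member as a value; and 5 per combination of directions in the 2 steps of the culture.

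Arrays were described by their control probe sets, which showed 2 sets of arrays that follow the replicate numbers. Across genes, deviations of arrays with the same number from their group means correlated with r = 0.283 between ESC and EpiSC-like, 0.0785 between ESC and day 7 and 0.0969 between EpiSC-like and day 7. The numbers were not taken to pair the samples. Since each set holds 1 array of each group, a block for the set leaves every fold change as it is and alters its error, and differences within each set are given beside list results. Alternatives to scaling, filter, choice of probe set, test, pseudocount and array set are described in the closing section.

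The fit was tested on simulated data made from the real gene means and residual spreads of the comparison of EpiSC-like cells with ESC. Over 20 runs with 200 of 18194 genes changed, 16.1% of genes changed 4-fold and 0.15% of genes changed 2-fold were called, with a mean of 0.55 false calls, and 95.7% and 76.7% of them had an unadjusted p under 0.05. In 20 further runs with the naive pluripotency list lowered by 1 on the log2 scale, camera found it in 20 runs at the preset correlation and in 0 with an estimated correlation, with means of 0.65 and 0 calls among the other tests. Genes were drawn independently of each other in all these runs. The runs therefore do not show how either correlation setting treats lists of correlated genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.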

Results

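The data are 6 arrays of Oct4-Venus-positive mouse cells, 2 each from undifferentiated ESC, from EpiSC-like cells at day 3 of SFEBq culture and from day 7 of the same culture. The design asks how cells sorted as positive for the Oct4 reporter differ along this neural differentiation, with Pecam1 gates that differed between the groups. Median signals of all probe sets lay between 63.99 and 76.3 intensity units. Replicates of a group correlated across the 18194 genes with r = 0.976 for ESC, 0.976 for EpiSC-like cells and 0.978 for day 7. Arrays of different groups correlated with r from 0.948 to 0.976. The 3 replicate 1 arrays and the 3 replicate 2 arrays formed 2 technical sets. Their highest signals were 30793 to 36841 and 63296 to 66643, and their hybridization controls 3172 to 4159 and 6668 to 8064. The poly-A controls, RNAs added to a sample before labelling, read 313.5 to 485.7 on 4 arrays. They read 45.1 on ESC replicate 2 and 50.0 on EpiSC-like replicate 2, so that day 7 replicate 2 stood apart from the other replicate 2 arrays. The log2 difference between the 3' and 5' probe sets of actin, which widens as RNA shortens, was 0.71 and 0.94 on the day 7 arrays and 0.46 to 0.58 on the other 4. The same difference for Gapdh was -0.12 and -0.18 on the day 7 arrays, within the range of -0.36 to 0.0054 on the other 4.

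**Figure D1:**
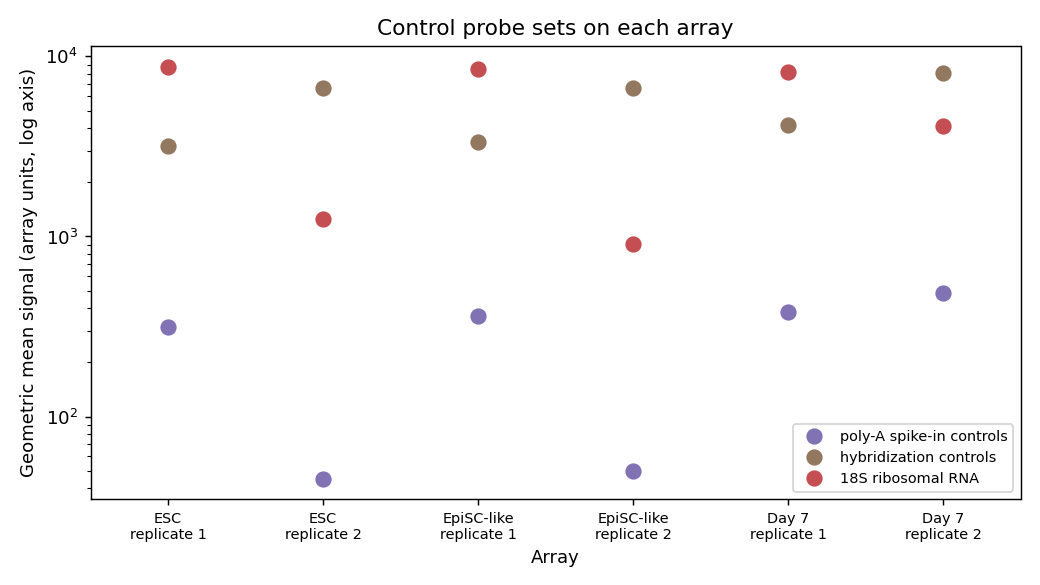
Geometric mean signal (log axis, array units) of poly-A spike-in controls, hybridization controls and 18S ribosomal RNA probe sets on each of the 6 arrays, 1 point per array and kind. Hybridization controls are higher on all 3 replicate 2 arrays, and poly-A controls are low only on ESC replicate 2 (45.1) and EpiSC-like replicate 2 (50.0).

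The reporter and gate genes did not pass in any of the 3 comparisons. Pou5f1 (NCBI gene 18999), which encodes Oct4, had a signal of 10991 ± 4333 (SD, n = 2) in ESC, 8083 ± 2601 in EpiSC-like cells and 7798 ± 1789 at day 7. Its log2 differences (± SE) were -0.42 ± 0.39 for EpiSC-like cells against ESC, -0.46 ± 0.39 for day 7 against ESC and -0.03 ± 0.39 for day 7 against EpiSC-like cells. The limma adjusted p-values were 0.680, 0.587 and 0.985. Pecam1 (NCBI gene 18613), the gene of the sorting antigen, read 536 ± 272 in ESC, 289 ± 159 in the Pecam1-negative EpiSC-like cells and 628 ± 197 at day 7. Its log2 differences in the 2 array sets were -0.835 and -0.899 for EpiSC-like cells against ESC, and 0.075 and 0.489 for day 7 against ESC. For day 7 against EpiSC-like cells they were 0.910 and 1.388. In the same order, its limma adjusted p-values were 0.480, 0.814 and 0.381.

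**Figure D2:**
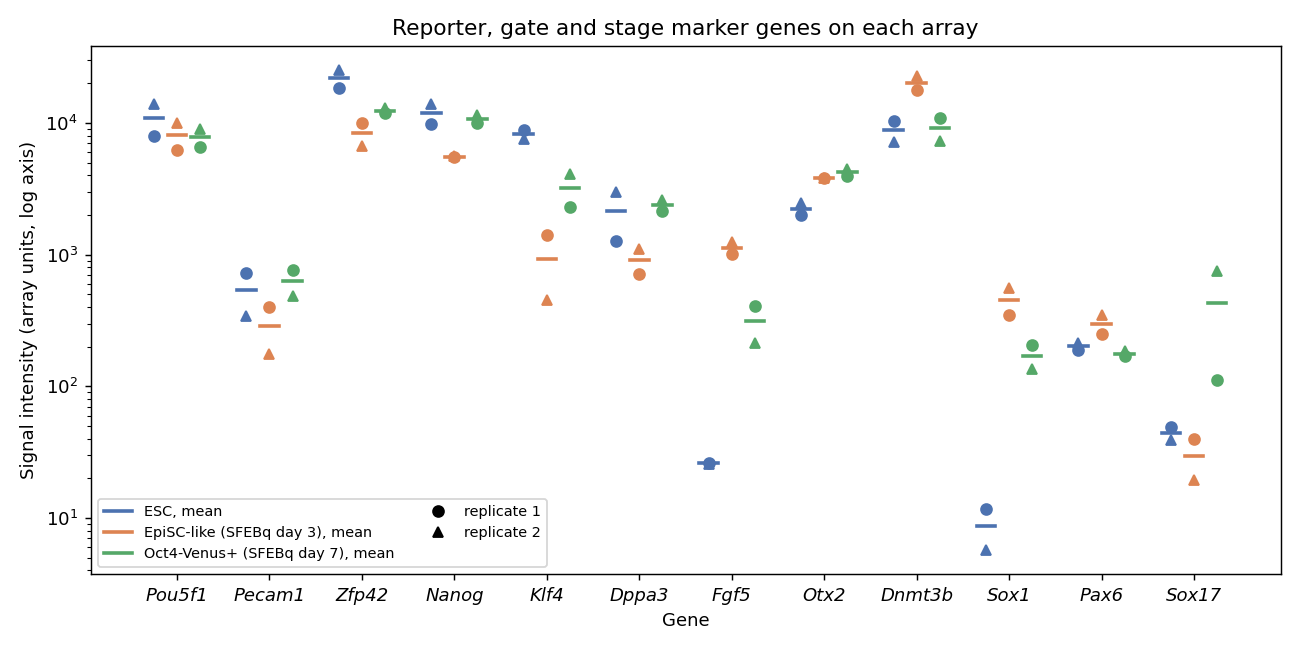
Signal (log axis, array units) of the reporter gene, the gate gene and 10 stage marker genes, with points for replicates 1 and 2 and a line for the mean of each group. Fgf5 and Sox1 lie above ESC in both later groups, Klf4 is lowest in EpiSC-like cells, and Sox17 reads 111.1 and 751.3 on the 2 day 7 arrays.

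EpiSC-like cells at day 3 had higher levels than ESC of the formative epiblast and the midbrain, hindbrain and caudal lists and lower levels of the naive pluripotency list (camera adjusted p = 7.44e-08, 0.000128 and 5.88e-19). None of the 3 passed with an estimated correlation (adjusted p = 0.446 for each). The largest log2 difference, with the pseudocount of 16, was that of Hoxb1 (NCBI gene 15407), a homeobox gene of the hindbrain, which rose from 6.84 ± 7.13 to 1027 ± 731 (5.35 ± 0.53, adjusted p = 0.0164). Pou3f1, a POU factor of the epiblast, rose from 176 ± 123 to 5418 ± 291 (4.98 ± 0.55, adjusted p = 0.0200). Fgf5, the growth factor that marks the postimplantation epiblast, rose from 26.0 ± 0.159 to 1126 ± 166 (4.76 ± 0.33, adjusted p = 0.0140). Spink1, a serine protease inhibitor, fell by 4.67 ± 0.61 (adjusted p = 0.0272). Socs3, the feedback inhibitor induced by LIF, fell by 4.08 ± 0.35 from 4110 ± 368 to 232 ± 62.2 (adjusted p = 0.0164). In all, 239 genes were higher and 106 lower of 18194 tested. In 345 of these 345 the change was at least 2-fold and in the same direction in both array sets. The genes were called on these same arrays, so this agreement is no separate evidence.

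Among the other large rises were Wt1 (4.65), the brain fatty acid binding protein Fabp7 (4.58), Ndnf (4.47), Hoxb2 (4.46), the neural transcription factor Sox1 (4.22), the carbonic anhydrase Car3 (4.10) and Cachd1 (3.87). Wt1 and Fabp7 started from ESC signals of 36.0 ± 46.9 and 17.2 ± 12.3. The other large falls included the transglutaminase Tgm1 (-4.04), the NF-kappa-B cofactor Bcl3 (-3.96), Pmel (-3.67), Serpinb6c (-3.44) and the naive factor Klf4 (-3.34). Ly6g6e (-3.21), Pla2g7 (-3.15) and the junction protein Jam2 (-3.14) completed them. Of the stage markers, 7 did not pass. The naive markers among them were Zfp42 (-1.40 ± 0.30, adjusted p = 0.0772), Nanog (-1.07 ± 0.26, adjusted p = 0.109) and Dppa3 (-1.13 ± 0.45, adjusted p = 0.286). Otx2 stood at 0.78 ± 0.23 (adjusted p = 0.169) and Dnmt3b at 1.22 ± 0.32 (adjusted p = 0.128). Pax6 stood at 0.52 ± 0.26 (adjusted p = 0.391) and Sox17 at -0.43 ± 0.77 (adjusted p = 0.860).

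Naive pluripotency genes fell as a group, with a median log2 difference of -1.53 over 20 members (-1.02 and -1.94 in the 2 array sets, camera adjusted p = 5.88e-19). Of the 20, 7 fell and 0 rose, and 18 fell when adjusted over the list alone. Besides Klf4 and Socs3, examples are Tfcp2l1 (-2.98 ± 0.32) and Tcl1 (-2.65 ± 0.29), and 20 of 20 values were below 0. One of the 20 is Pecam1 (-0.87), the gene of the sorting antigen. EpiSC-like cells were sorted as Pecam1-negative, and the protocol names ESC as CD31-positive. The fall of this list therefore cannot be told apart from the gates. Formative and primed epiblast genes were higher with a median of 1.31 (1.09 and 1.58, adjusted p = 7.44e-08). Of these, 7 of 20 rose, and 13 adjusted over the list alone. They include Fgf5, Pou3f1, the Wnt effector Lef1 (3.82 ± 0.57) and Sall2 (3.56 ± 0.35).

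The midbrain, hindbrain and caudal list was higher (median 0.85, 0.70 and 1.21 in the sets, adjusted p = 0.000128). Its 4 called members of 15 were Hoxb1, Hoxb2, Irx3 (3.11 ± 0.22) and Gbx2 (1.83 ± 0.32), and 6 rose adjusted over the list alone. The retinoic acid list was higher (median 1.10, 0.23 and 2.29, adjusted p = 0.00117). Here 4 of 10 rose, and adjusted over the list alone 4 rose and 1 fell. The 4 were Hoxb1, the retinaldehyde reductase Dhrs3 (3.20 ± 0.27), Stra8 (3.13 ± 0.27) and the receptor gene Rarb (2.00 ± 0.24). Pan-neural progenitor genes were higher (median 0.58, 0.52 and 1.22, adjusted p = 0.00351). Of 15, 2 rose, Fabp7 and Prom1 (3.16 ± 0.24), and 4 adjusted over the list alone. The Wnt response list was higher (median 0.39, 0.43 and 0.54, adjusted p = 0.0132). Of 11, 2 rose, Lef1 and Sp8 (2.77 ± 0.25), and 3 adjusted over the list alone. Only 5 of the 11 had the same sign in both array sets. Lef1 is also in the formative list, and Hoxb1 is in both the midbrain, hindbrain and caudal list and the retinoic acid list. The results of these lists are therefore not fully separate.

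A further 3 lists passed with smaller shifts. p53 targets were higher (median 0.39, 0.57 and 0.26 in the sets, adjusted p = 0.00773) with 0 of 14 called over all genes and 3 rises adjusted over the list alone. Cdkn1a, a cell cycle inhibitor gene, stood at 1.40 ± 0.26. The list did not pass without EpiSC-like replicate 1 (adjusted p = 0.143). Imprinted genes were higher (median 0.67, 0.18 and 1.07, adjusted p = 0.0152), although the only member of 18 called, Phlda2, fell by 1.58 ± 0.23. Adjusted over the list alone 4 rose and 1 fell. The list did not pass without ESC replicate 2 (adjusted p = 0.0825) or EpiSC-like replicate 2 (adjusted p = 0.118). The trophoblast list was lower (median -0.30, -0.36 and -0.21, adjusted p = 0.0466) with 0 of 12 called over all genes and 1 fall adjusted over the list alone. It did not pass with arrays centred on their median (adjusted p = 0.0543) or with quantile normalization (adjusted p = 0.0592). Nor did it pass without ESC replicate 2 (adjusted p = 0.141) or EpiSC-like replicate 1 (adjusted p = 0.323).

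With an estimated correlation all 9 list calls of this comparison were lost (adjusted p = 0.537 for trophoblast and 0.446 for the other 8). The simulated list lowered 2-fold was also missed with that setting, but its genes were drawn independently of each other. It therefore does not show whether that setting wrongly loses lists of correlated genes. The other 20 lists did not pass (camera adjusted p from 0.0908), with medians from -0.27 to 0.47. Of their members 5 rose and 2 fell. The 5 were Sox1, the germ cell gene Dazl (1.54 ± 0.27), Snai2 (1.70 ± 0.29), Col1a2 (2.00 ± 0.34) and Tagln (3.08 ± 0.54). The 2 were Bmp4 (-2.56 ± 0.40) and the neuronal microtubule regulator gene Stmn2 (-3.02 ± 0.37). The median and the mean of the anterior neuroectoderm list (-0.02 and 0.39) and of the endoderm list (0.02 and -0.22) differed in sign.

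With the array set as a block 0 genes passed in limma (smallest adjusted p = 0.0505, 3369 genes at an unadjusted p under 0.05 against 2904 without the block), and 0 passed with a pseudocount of 1, without ESC replicate 2 or without either EpiSC-like array. The counts were 54 higher and 9 lower without ESC replicate 1, 29 and 12 without either day 7 array, and 458 and 214 among genes at or above the 25th percentile of mean signal.

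**Figure D3:**
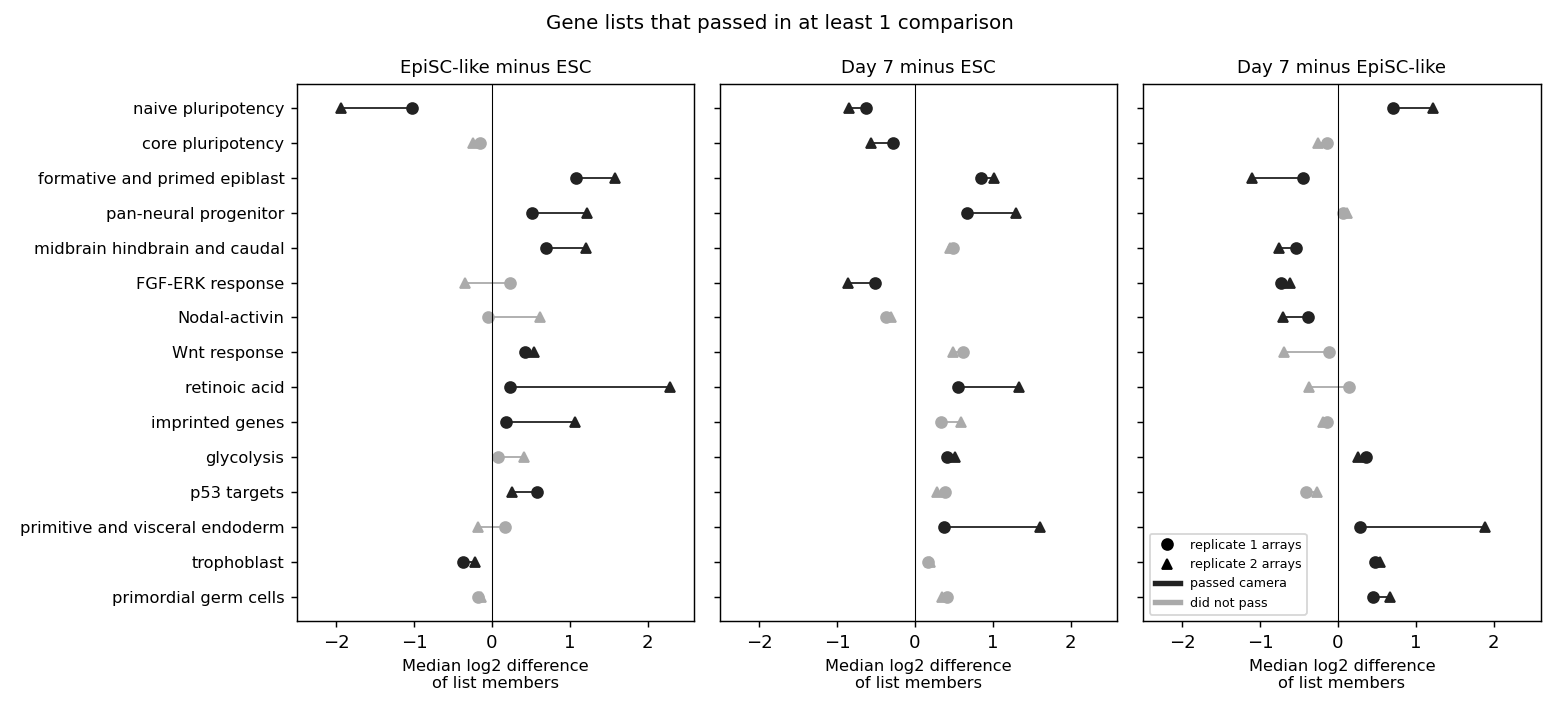
Median log2 difference over the members of each list that passed in at least 1 comparison, in panels for the 3 comparisons, with a point for the replicate 1 arrays, a triangle for the replicate 2 arrays and dark symbols for lists that passed camera. The naive list lies below 0 in both sets for EpiSC-like minus ESC (-1.02 and -1.94) and above 0 in both for day 7 minus EpiSC-like (0.70 and 1.22), while the endoderm list is at 0.28 and 1.89 in the latter.

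At day 7 the Oct4-Venus-positive cells had higher levels than ESC of the pan-neural progenitor list (median log2 difference 1.04, camera adjusted p = 0.000232) and lower levels of the FGF-ERK response list (-0.50, camera adjusted p = 0.00258). Neither passed with an estimated correlation (adjusted p = 0.446 for both). Day 7 cells and ESC also differed in dissociation, recovery time and staining. Neither the gene calls nor the list results of this comparison can be told apart from that handling. Fabp7 had the largest log2 difference with the pseudocount of 16, and rose from 17.2 ± 12.3 to 1088 ± 598 (4.99 ± 0.44, adjusted p = 0.0291). Nhlh2, a neuronal helix-loop-helix factor (4.72 ± 0.70, adjusted p = 0.0451), and the nuclear receptor gene Nr2f1 (4.24 ± 0.54, adjusted p = 0.0371) followed. The glycogen phosphorylase gene Pygl rose from 102 ± 7.38 to 1878 ± 364 (3.99 ± 0.26, adjusted p = 0.0221). The homeobox gene Meis2 rose from 119 ± 15.5 to 2063 ± 454 (3.94 ± 0.31, adjusted p = 0.0221). Spry4, an inhibitor of receptor tyrosine kinase signalling, fell by 3.76 ± 0.40 from 2819 ± 1081 to 187 ± 28.5 (adjusted p = 0.0291). S100a6 fell by 3.53 ± 0.28 (adjusted p = 0.0221). Id1, a BMP target, fell by 3.45 ± 0.39 (adjusted p = 0.0291). In all, 137 genes were higher and 52 lower of 18194. In 189 of these 189 the change was at least 2-fold and in the same direction in both array sets. Here too the calls came from these same arrays, so the agreement is no separate evidence. Nhlh2 read 206.4 and 985.5 on the 2 day 7 arrays, and Nr2f1 174.6 and 610.8. Their ESC means of 1.87 and 2.30 lay far below the pseudocount, which compresses their log2 differences more than that of Fabp7, so the order of these 3 genes is not a ranking of fold changes.

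Ndrg1 (3.42), Asb9 (3.38), Nsg2 (3.37), Cyp26b1, an enzyme that degrades retinoic acid (3.28), and Tox3 (3.13) completed the 10 largest rises. Tgm1 (-3.44), Mras (-3.21), Bcl3 (-2.98), Pmel (-2.97), Myc (-2.81), Bmp4 (-2.70) and Cltb (-2.60) completed the 10 largest falls. Of the stage markers, Fgf5 (2.90 ± 0.33, adjusted p = 0.0291) and Sox1 (2.90 ± 0.33, adjusted p = 0.0291) rose. The naive markers did not pass. Zfp42 stood at -0.81 ± 0.30 (adjusted p = 0.225), Nanog at -0.13 ± 0.26 (adjusted p = 0.843), Klf4 at -1.42 ± 0.55 (adjusted p = 0.246) and Dppa3 at 0.28 ± 0.45 (adjusted p = 0.791). Nor did Otx2 (0.92 ± 0.23, adjusted p = 0.117), Dnmt3b (0.05 ± 0.32, adjusted p = 0.955), Pax6 (-0.17 ± 0.26, adjusted p = 0.776) or Sox17 (2.38 ± 0.77, adjusted p = 0.184).

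The naive pluripotency list was lower at day 7 than in ESC (median -0.74, -0.62 and -0.85 in the sets, camera adjusted p = 1.10e-05). Of its 20 members 1 fell, Klf5 (-2.36 ± 0.37), and 6 adjusted over the list alone. Pecam1 (0.28) is among the 20, and the gates for it differed between day 7 and ESC. The core pluripotency list was lower (median -0.46, -0.28 and -0.56, adjusted p = 0.00564) with 0 of 15 called, over all genes or adjusted over the list alone. Dppa2 stood at -1.09 ± 0.24 and Lin28a at -1.05 ± 0.45. The list did not pass without ESC replicate 2 (adjusted p = 0.103) or with the spike-in level as a block, a setting chosen after the data were seen (adjusted p = 0.0510). The pan-neural progenitor list was higher (median 1.04, 0.67 and 1.29, adjusted p = 0.000232). Of 15, 2 rose, Fabp7 and Pax3 (2.36 ± 0.34), and 4 adjusted over the list alone. The formative list was higher (median 1.05, 0.85 and 1.01, adjusted p = 0.000354) with Fgf5 as its 1 called member of 20. Adjusted over the list alone 10 rose and 2 fell.

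FGF-ERK response genes were lower (median -0.50, -0.51 and -0.85 in the sets, adjusted p = 0.00258). Spry4 and Spry2 (-2.04 ± 0.24) fell and the phosphatase gene Dusp5 rose by 2.43 ± 0.34. Adjusted over the list alone 5 of 13 fell and 1 rose. The retinoic acid list was higher (median 1.23, 0.55 and 1.34, adjusted p = 0.00438). Of 10, 1 rose, Stra8 (1.90 ± 0.27), and 3 adjusted over the list alone. Glycolysis genes were higher (median 0.50, 0.41 and 0.51, adjusted p = 0.00484) with 0 of 13 called, over all genes or adjusted over the list alone. Of the 13 values 12 were above 0, such as that of the glucose transporter gene Slc2a1 (1.09 ± 0.28). The list did not pass without ESC replicate 1 (adjusted p = 0.0807).

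The primitive and visceral endoderm list was higher (median 1.08, 0.38 in the first and 1.60 in the second set, adjusted p = 0.00162). Over all genes 0 of 18 members were called, and 5 rose adjusted over the list alone. Its transcripts differed between the 2 day 7 arrays: Col4a1 read 1853 and 7417, Ttr 89.6 and 778.6, and Afp 64.3 and 471.3. The list did not pass without day 7 replicate 2 (adjusted p = 0.110), among genes at or above the median (adjusted p = 0.144) or with the spike-in level as a block (adjusted p = 0.130). With an estimated correlation all 8 list calls of this comparison were lost (adjusted p from 0.446 to 0.629). The other 21 lists did not pass (camera adjusted p from 0.0529), with medians from -0.38 to 0.56. Of their members 8 were called higher and 5 lower. The 8 include Zic1 (3.00 ± 0.39), Irx3 (2.89 ± 0.22), Lhx2 (2.54 ± 0.34), Ier3 (2.43 ± 0.27), Dazl (2.40 ± 0.27) and Id4 (2.05 ± 0.24). The 5 include Phlda2 (-1.52 ± 0.23) and Stmn2 (-2.45 ± 0.37). The median and the mean of the fibroblast list (-0.18 and 0.07) differed in sign. These lists compare arrays that also differed in the actin 3' to 5' difference, 0.71 and 0.94 at day 7 against 0.51 and 0.53 in ESC, while that of Gapdh, -0.12 and -0.18, lay within the range of the other arrays.

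Centring the arrays on their median moved the median difference of all genes between day 7 and ESC from 0.02 to -0.15. The split of calls went from 137 higher and 52 lower to 96 and 74, and to 91 and 55 with quantile normalization. With the array set as a block 0 genes passed in limma (smallest adjusted p = 0.0664, 3920 genes at an unadjusted p under 0.05 against 3331), and 0 passed with a pseudocount of 1. Without day 7 replicate 1 the counts were 10 and 0, without any other single array 0, and among genes at or above the 25th percentile 427 and 140.

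The genes called at day 3 and those called at day 7 overlapped: 55 were higher than in ESC at both times and 23 lower, against 1.80 and 0.303 for independent lists. Both comparisons use the ESC arrays, which raises such an overlap. Simulations of groups with no effect gave a mean of 0.01 genes called in both. They hold no changed genes, so how much of the overlap the shared arrays account for was not tested. Across genes, the 2 sets of differences from ESC correlated with r = 0.594 (covariance 0.237) where 100 simulations of groups with no effect gave a mean of 0.499 (covariance 0.0588). With day 3 read in one array set and day 7 in the other, so that no array was shared, r was 0.344 and 0.345. Genes are not independent replicates in these correlations. Genes with a group mean at or above the median were also chosen as at least 2-fold higher at day 3 in one set and read in the other. There their median log2 difference from ESC was 1.60 at day 3 and 1.00 at day 7 in the second set, and 1.04 and 0.64 in the first. For genes chosen as at least 2-fold lower these medians were -1.53 and -0.75, and -0.93 and -0.60. Day 3 and day 7 share the ESC array of the set they were read in.

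Between day 3 and day 7 of the culture, the midbrain, hindbrain and caudal list and the formative list were lower and the naive list was higher (camera adjusted p = 0.00202, 0.00138 and 4.94e-09). None of the 3 passed with an estimated correlation (adjusted p = 0.446 for each). Dissociation, recovery time and staining also differed between day 3 and day 7 cells. The list results and gene calls of this comparison cannot be told apart from that handling. In limma 7 single genes passed. Gad1, which encodes an enzyme of GABA synthesis, went from 31.9 ± 10.5 to 938 ± 1.92 (4.33 ± 0.39). Ndrg1, a gene raised by stress and low oxygen, went from 234 ± 84.2 to 3591 ± 631 (3.88 ± 0.34). The protease inhibitor gene Serpinb1a went from 2.76 ± 0.790 to 143 ± 30.1 (3.07 ± 0.28) and the stress response gene Gadd45b from 422 ± 21.1 to 2692 ± 247 (2.63 ± 0.22). Gbx2, a homeobox gene of the anterior hindbrain, fell by 3.65 ± 0.32 from 1440 ± 378 to 97.7 ± 6.25. Myrf fell by 2.93 ± 0.26 and Tnfsf11 by 2.92 ± 0.26. The limma adjusted p was 0.0495 for each of the 7.

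Gbx2 and Tnfsf11 had risen from ESC to day 3, and Serpinb1a had fallen. This makes 2 genes up then down and 1 down then up, against 0.0394 and 0.0233 for independent lists. Both steps use the EpiSC-like arrays, which raises such counts. In limma 0 genes moved the same way in both steps, against 0.0525 up then up and 0.0175 down then down for independent lists. With so few genes called in the second step, this 0 does not show that changes reversed. Of the 239 genes higher at day 3, 205 read lower at day 7 than at day 3, 105 by at least 2-fold. Of the 106 lower at day 3, 93 read higher, 52 by at least 2-fold. Chance at the shared arrays also raises these numbers. With the day 3 change read in one set and the later change in the other, the changes correlated with r = -0.203 and -0.230 across genes.

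The naive list was higher at day 7 than at day 3 (median 0.95, 0.70 and 1.22 in the sets, camera adjusted p = 4.94e-09). Over all genes 0 of 20 members were called, 10 rose adjusted over the list alone, and 19 values were above 0. Pecam1 (1.15) is among the 20, and of these 2 groups only the day 3 cells were sorted as Pecam1-negative. The rise of this list therefore cannot be told apart from the gates. Tcl1 stood at 1.92 ± 0.29, Tfcp2l1 at 1.89 ± 0.32 and Nanog at 0.95 ± 0.26. The formative list was lower (median -0.79, -0.44 and -1.11, adjusted p = 0.00138). Of 20 members 0 were called, and adjusted over the list alone 6 fell and 1 rose. Pou3f1 stood at -2.65 ± 0.55, Sall2 at -2.02 ± 0.35 and Fgf5 at -1.86 ± 0.33. The midbrain, hindbrain and caudal list was lower (median -0.63, -0.54 and -0.76, adjusted p = 0.00202). Gbx2 fell, and Hoxb1 stood at -3.50 ± 0.53 and Hoxb2 at -2.23 ± 0.47. Adjusted over the list alone 4 of 15 fell and 1 rose.

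FGF-ERK response genes were lower than at day 3 (median -0.64, -0.74 and -0.61 in the sets, adjusted p = 0.00162) with 0 of 13 called and 5 falls adjusted over the list alone. Spry4 stood at -1.63 ± 0.40. The list did not pass without EpiSC-like replicate 1 (adjusted p = 0.0751). The Nodal-activin list was lower (median -0.44, -0.39 and -0.70, adjusted p = 0.0303) with 0 of 9 called and 1 fall adjusted over the list alone. Lefty1 stood at -2.08 ± 0.38. This list did not pass with the array set as a block (adjusted p = 0.0527) or with quantile normalization (adjusted p = 0.0580). It did not pass without EpiSC-like replicate 2 (adjusted p = 0.111) or day 7 replicate 1 (adjusted p = 0.0918) either.

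The endoderm list was higher at day 7 than at day 3 (median 1.09, 0.28 and 1.89 in the sets, adjusted p = 1.12e-05) with 0 of 18 called and 8 rises adjusted over the list alone. Sox17 stood at 2.82 ± 0.77 (adjusted p = 0.191) and read 111.1 and 751.3 on the 2 day 7 arrays, and Lama1 stood at 2.99 ± 0.76. Primordial germ cell genes were higher (median 0.58, 0.45 and 0.66, adjusted p = 0.00236) with 0 of 15 called, over all genes or adjusted over the list alone. Dppa3 stood at 1.40 ± 0.45 (adjusted p = 0.244) and Prdm14 at 1.14 ± 0.30. Both genes are also members of the naive list, so the 2 list results are not separate evidence. Trophoblast genes were higher (median 0.49, 0.48 and 0.54, adjusted p = 0.00715) with 0 of 12 called and 4 rises adjusted over the list alone. Ascl2 stood at 2.28 ± 0.41 and the keratin gene Krt18 at 2.06 ± 0.46. The trophoblast list did not pass without EpiSC-like replicate 1 (adjusted p = 0.0870) or day 7 replicate 2 (adjusted p = 0.0517). Glycolysis genes were higher (median 0.29, 0.36 and 0.25, adjusted p = 0.0205) with 0 of 13 called and 2 rises adjusted over the list alone. Hk1 stood at 1.30 ± 0.26 and Pfkp at 1.21 ± 0.26. Glycolysis did not pass without EpiSC-like replicate 1 (adjusted p = 0.404) or day 7 replicate 2 (adjusted p = 0.124).

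With an estimated correlation all 9 list calls between day 3 and day 7 were lost (adjusted p = 0.548 for glycolysis, 0.467 for endoderm and 0.446 for the other 7). The other 20 lists did not pass (camera adjusted p from 0.0544), with medians from -0.31 to 0.42 and 0 members called. In BMP response, DNA methylation machinery, primitive streak and neural crest, the median, mean and test differed in sign. These lists compare arrays that also differed in the actin 3' to 5' difference, 0.71 and 0.94 at day 7 against 0.58 and 0.46 at day 3, while that of Gapdh lay within the range of the other arrays. Of the stage markers, Zfp42 (0.59 ± 0.30, adjusted p = 0.440), Klf4 (1.92 ± 0.55, adjusted p = 0.206) and Otx2 (0.14 ± 0.23, adjusted p = 0.845) did not pass. Neither did Dnmt3b (-1.17 ± 0.32, adjusted p = 0.189), Sox1 (-1.32 ± 0.33, adjusted p = 0.171) or Pax6 (-0.69 ± 0.26, adjusted p = 0.309).

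With the array set as a block 0 genes passed in limma (smallest adjusted p = 0.124, 3055 genes at an unadjusted p under 0.05 against 2564), and 0 passed with quantile normalization, with a pseudocount of 1 or without any 1 of the 6 arrays. Among genes at or above the 25th percentile 89 were higher and 55 lower.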

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

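The spike-in block (the replicate 1 arrays, the low spike-in pair and day 7 replicate 2 as 3 levels) was chosen after the data were seen, and all other settings before. Counts are given as genes higher and lower in EpiSC-like cells against ESC, at day 7 against ESC and at day 7 against EpiSC-like cells, then the sum of genes that changed in both steps, from 239 and 106, 137 and 52, 4 and 3, and 3. Of the named genes' 75 calls, 71 were kept with median centring, 56 with quantile normalization, 52 against a 1.2-fold threshold and 0 with either block or a pseudocount of 1. None was called in the other direction in the settings that tested it; 46 of the 75 were tested at genes at or above the median and 73 without probe sets shared between transcripts, and a block for the array set cannot change a fold. Of the list calls 0 were called in the other direction. Dim genes were tested with the rest, and counts moved with the filter on them and with the pseudocount; what share low signal has in this was not tested.

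Counts went up with genes at or above the 25th percentile (458 and 214, 427 and 140, 89 and 55, then 61), at or above the median (451 and 283, 551 and 292, 195 and 120, then 123), with an intensity trend and robust moderation (504 and 266, 537 and 236, 145 and 93, then 98) and with a pseudocount of 64 (447 and 222, 474 and 208, 124 and 84, then 83). The first pair of settings tests fewer genes and fits the spread without dim ones, by construction; the cause was not tested.

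Counts went down to 0 throughout with the array set as a block, with a pseudocount of 1 and with the spike-in block, where limma still gave 1977 to 3920 genes at an unadjusted p under 0.05. With only the 4 arrays compared they were 29 and 12, then 0 and 0, 0 and 0, and 0 (unadjusted 2677, 3200 and 2545), and over all probe sets 101 and 28, 0 and 0, and 0 and 0 (unadjusted 5337, 6811 and 5306). Against a 1.2-fold threshold they were 139 and 61, 57 and 20, 0 and 0, and 0 (unadjusted 2067, 2266 and 1668). The third comparison and the genes of both steps went to 0 with quantile normalization and without probe sets shared between transcripts (unadjusted 2689 and 2462), quantile normalization gave 91 higher at day 7 against ESC, and median centring gave 6 lower at day 7 against EpiSC-like cells. Fewer residual degrees of freedom come with the blocks and the smaller fits by construction; for the others the cause was not tested.

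Leaving out 1 array at a time, with the lone array assumed to vary like the other groups, gave 0 to 54 higher and 0 to 12 lower in EpiSC-like cells against ESC, 0 to 10 higher and 0 to 0 lower at day 7 against ESC, and 0 to 0 for the third comparison and the genes of both steps. The number of list calls, 9, 8 and 9, ranged over the same settings from 7 to 12, 8 to 11 and 7 to 11. It was 5 for EpiSC-like cells against ESC at genes at or above the median, where BMP response passed, 4 of the 9 calls passed, the imprinted list did not, and the other 4 (midbrain hindbrain and caudal, Wnt response, retinoic acid and trophoblast) had too few members left to be tested. It was 0, 0 and 0 both with an estimated correlation and with fry. For EpiSC-like cells against ESC, the Wnt response list did not pass with the mean of probe sets (adjusted p = 0.0603), nor the imprinted list at genes at or above the median (adjusted p = 0.0728).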

Other observations

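Before their results were seen, tests were written for the explanations by a separate preparation and by oxygen. So were the endoderm test of array set scale and the test of several cell kinds. The tests of handling, of the neuron part, of a share of ESC and of the gates were chosen after, as were the set differences by group. Of the 29 lists, 14 passed in none of the 3 comparisons. Their median log2 differences, for EpiSC-like cells against ESC, day 7 against ESC and day 7 against EpiSC-like cells, are given as values. Among neural and ectodermal lists they were -0.02, 0.16 and 0.00 for anterior neuroectoderm, 0.19, 0.37 and 0.39 for neurogenesis and neurons, and 0.06, 0.42 and -0.01 for neural crest. Signalling lists gave 0.20, 0.37 and 0.04 for Notch and -0.11, -0.10 and -0.13 for BMP response. The primitive streak list gave 0.19, 0.25 and -0.02, fibroblasts 0.47, -0.18 and -0.23, and blood and endothelium 0.20, 0.18 and 0.18. General cell functions gave 0.04, -0.07 and -0.08 for the cell cycle, -0.14, -0.20 and -0.04 for the respiratory chain, -0.07, 0.14 and 0.20 for ribosomal proteins, -0.23, -0.25 and 0.01 for DNA methylation, -0.07, -0.38 and -0.12 for 2-cell-like genes, and 0.14, 0.073 and 0.22 for dissociation genes.

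Genes known to respond to low oxygen were higher at day 7. A list of 23 targets of the oxygen-sensing factor HIF, 22 of them measured and 0 in the fixed lists, was written after Ndrg1 and the glycolysis list had been seen and before its own values were. Against ESC its median was 1.12 (0.84 and 1.46 in the array sets), 19 of 22 were above 0 and 8 rose, among them the mitophagy gene Bnip3 (2.39), the collagen hydroxylase genes P4ha2 (2.44) and Plod2 (2.45), the vasodilator gene Adm (2.19) and Ddit4 (2.07), an inhibitor of mTORC1. Against EpiSC-like cells the median was 0.82 (0.78 and 0.85) with 0 called and 19 above 0. The 2 camera tests, adjusted over 9, gave adjusted p = 2.55e-10 for each, and with an estimated correlation adjusted p = 0.0341 for each. Between EpiSC-like cells and ESC the median was 0.31 (adjusted p = 0.0728). The day 7 arrays also had the higher actin 3' to 5' differences (0.71 and 0.94 against 0.46 to 0.58), while those of Gapdh (-0.12 and -0.18) lay within the range of the other arrays.

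The pattern was first seen in Ndrg1 (3.42) and the glycolysis list, and the HIF list tested it on genes not yet seen, but on the same arrays. The list is therefore no evidence from further samples. The poly-A controls of the second day 7 array stood apart from those of the other replicate 2 arrays, and the reason is not known. A separate preparation of that array as the cause is argued against by the first array set, where the median of the list was 0.84. Oxygen-limited transcription in the day 7 aggregates may contribute: it needs such further targets to be higher, and the larger unadjusted camera p was 5.66e-11, but the list does not tell low oxygen from other causes that raise the same genes. Handling stays open, since the dissociation and immediate early list, with a median of 0.073 against ESC, had quartiles of -0.79 and 0.92, and since enzyme, recovery time and staining all differed with the day.

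The second day 7 array read higher for endoderm transcripts (Col4a1 1853 and 7417, Ttr 89.6 and 778.6) and neuron transcripts than the first. Over a further list of 16 neuron genes the second array read higher by a median of 0.87 at day 7 (16 of 16 genes), 0.01 in EpiSC-like cells and -0.68 in ESC. The median of day 7 less the mean of the other groups was therefore 1.44 (95% bootstrap interval 1.12 to 1.94), much of it from the ESC pair. Against EpiSC-like cells alone it was 1.11 (0.69 to 1.86). The bootstrap resampled genes, with 1 array per group and set, so these intervals do not hold the spread between arrays. For the neuron part the values argue against one constant log2 difference between the sets in every group, but not against variation of single arrays. A set difference that changes with signal was not tested. Some of these genes were dim on the ESC arrays, such as Snap25 (18.1 and 1.9) and Ebf3 (15.2 and 3.9). Others were not, such as Nefl (1320.2 and 759.3). A further list of 15 endoderm genes gave 0.30 (-0.16 to 1.61). On it the second array read higher by a median of 0.41 at day 7 (13 of 15 genes), 0.11 in EpiSC-like cells and -0.01 in ESC. Day 7 less EpiSC-like cells alone gave 0.39 (0.06 to 1.81), and day 7 less ESC alone 0.42 (-0.33 to 1.83). Scale stays open for the endoderm part. More differentiated cells of several kinds in the second sort may contribute to the neuron part. However, the neuron value of 1.44 is not due to the day 7 arrays alone. The endoderm value of 0.30 did not reach the 0.5 this explanation needed. How far the sort for Venus removed such cells was not tested.

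The naive list at day 7 had a median below ESC (-0.74) and above EpiSC-like cells (0.95), and 16 of its 20 genes read between the 2 groups, 3 above ESC and 1 below EpiSC-like cells, with 1 called against ESC and 0 against EpiSC-like cells. A share of unchanged ESC in an otherwise EpiSC-like fraction would put every gene at one fraction of the way back to ESC on the linear scale, but among the 10 naive genes at least 2-fold lower at day 3 in both sets the fractions ran from -0.15 for Nr0b1 to 0.58 for Fbxo15, and differed between genes by more than between array sets (permutation p = 0.0184, 100000 permutations), which argues against it as the whole cause. The different gates stay open: the naive median of -0.74 against ESC at day 7, where no Pecam1 gate is named, does not decide, since the sorting protocol names ESC as CD31-positive. Neither the fall from ESC nor the return from day 3 to day 7 can be told apart from the gates, because cells of one gate at every stage were not analysed here. A mix of cells with different histories was not tested.

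Xist, the RNA that coats the inactive X chromosome, was chosen after its values were seen. It read 508.9 and 387.1 in ESC, 1166.2 and 1002.1 in EpiSC-like cells and 346.7 and 323.1 at day 7. Its log2 difference was 1.25 for EpiSC-like cells against ESC (limma adjusted p = 0.0635). For day 7 against EpiSC-like cells it was -1.65 (limma adjusted p = 0.0863). Among genes of the Y chromosome, Eif2s3y read 3404.9 to 4783 and Uty 456 to 1234.9 over all arrays, whereas Kdm5d was dim (11 to 79.3). The Xist values are therefore not read as inactivation of an X chromosome, which was not tested.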
